A study of Arabidopsis thaliana with 9 samples.

How the data were processed

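Transcript levels were measured on 9 single-colour Affymetrix expression arrays of Arabidopsis thaliana in the Col-0 background. The 3 genotypes were wild type, ssrp1-2 and spt16-1, with 3 arrays each that the labels call biological replicates. Per the labels, each array carried RNA from pooled aerial parts of 10-day-old seedlings grown on 0.5 MS plates, about 100 mg of tissue per pool, and 200 ng of total RNA was labelled with biotin. The labels do not say whether the pools came from separate plates or sowings, so p-values measure the spread between these pools.

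The deposited values are log2 expression values, 1 per probe set and array. They were made with RMA (version not given) in Affymetrix Expression Console 1.3, per the submitters' processing notes. RMA subtracts background, normalizes the arrays to a common distribution and summarises the probes of a probe set, so differences in total RNA between genotypes would not be visible in these values. Scanner files and probe-level data were not used here. Array medians were close to each other before any step of the re-analysis, and no further scaling was applied to the main values.

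All 28501 probe sets were tested, and 0 were identified as controls and removed. GEO's platform annotation paired 16722 of them with 1 gene and 759 with several genes, and 11020 were unnamed in the annotation used here. Of the probe sets with 1 gene, 16574 matched a gene of the RefSeq annotation of TAIR10.1 and 148 did not. Matched and unmatched together, they covered 16550 distinct genes, 146 of them with more than 1 probe set. RefSeq served only for names, neighbours and the genome a gene belongs to, and no coordinates are given because the build behind the probe design is not given in the sources used here. No gene was named from a probe set with several genes. SSRP1 and SPT16 had 0 named probe sets, so the level of the mutated genes was not analysed here and the genotype labels had no check of that kind. Values of 387 probe sets were identical to those of an earlier probe set.

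Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) in 1 fit of all 9 arrays, which gave 6 residual degrees of freedom, 2.76 prior degrees of freedom and a median moderated SD of 0.135 on the log2 scale. Adjusted p-values are Benjamini-Hochberg values over all 28501 probe sets within a comparison, and a probe set passed when the value was under 0.05. Errors after ± are SDs over the 3 arrays of a genotype. An exact permutation test of 3 arrays against 3 cannot give a p below 0.1 and was not used. The limma tests use a spread shared across probe sets, except the unmoderated test among the alternatives. The number of arrays limits the precision, since array intensities carry no counting depth.

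Gene groups came from 28 lists written before the data were examined, 26 of them by gene (384 genes, 57 with a named probe set) and 2 by organelle genome. Organelle genes were recognised by the plastid in RefSeq and, for the mitochondrion, by gene symbols that RefSeq did not match. Lists with at least 4 measured genes were tested with camera (preset correlation 0.01, 1 probe set per gene, Benjamini-Hochberg over the lists of a comparison); 7 qualified, 13 had 1 to 3 measured genes and 8 had none. Camera was repeated with an estimated correlation, and fry tested each list without reference to other genes. A further 28 lists of gene families were defined from the annotation after its coverage was seen and before any fold change was seen.

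Genes named in the text followed a rule also written before the data were examined. It took SSRP1 and SPT16; per mutant the 10 higher and 10 lower genes with the largest log2 change among those that passed and whose arrays did not overlap between genotypes, with 5 and 5 for ssrp1-2 against spt16-1; the 4 members of each list with the smallest p per comparison; and the 5 higher and 5 lower genes with the largest change in both mutants. Other genes are named where a count is small, and are then said to lie outside the rule.

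The overlap of the mutants was set beside unchanged groups simulated 100 times against a shared wild-type group that was also simulated. The alternatives were a replicate block, an intensity trend, robust moderation, array weights, other scalings, a filter on the lowest 25% of values, fits of 2 groups, an unmoderated test, a 2-fold minimum and leaving out each array in turn. On simulated data for ssrp1-2 against wild type with 28501 probe sets, the test recovered 38.8% of changes of 0.5 on the log2 scale, 89.6% of changes of 1 and 100% of changes of 2, with 6 false calls among 158. In 100 simulated draws for that comparison without any change, camera called a list in 2 draws with the preset correlation and in 0 with the estimated one. In a simulated run with 1 list shifted, camera with the preset correlation called 2 lists, the shifted one among them. Genes were drawn independently in these simulations, so false calls in correlated lists were not tested. In the data the estimated correlation was 0.138 for the anthocyanin list and 0.411 for chloroplast-encoded genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.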

Results

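Transcript profiles of aerial parts were compared between wild-type Arabidopsis seedlings and seedlings carrying the ssrp1-2 or the spt16-1 allele. SSRP1 and SPT16 are the subunits of FACT, a histone chaperone that assists RNA polymerase II on chromatin, and the comparison asks how transcript levels differ when either subunit is affected. Each genotype had 3 arrays of 28501 probe sets, with array medians between 4.95 and 4.98 on the log2 scale. Arrays of 1 genotype correlated across probe sets at r = 0.992 to 0.994 over 9 pairs, and arrays of different genotypes at 0.989 to 0.992 over 27 pairs; probe sets are not independent replicates. Expression of the mutated genes was not analysed here. Across the 3 genotypes, 892 probe sets differed by limma's F test. That count moved by over 1.5 times without any 1 array: 541, 515 and 496 without wild-type replicates 1, 2 and 3, 579, 558 and 499 without those of ssrp1-2, and 568, 553 and 563 without those of spt16-1. It was 548 with a replicate block and 1536 with an intensity trend.

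Measured anthocyanin genes were lower in ssrp1-2 than in wild type. The anthocyanin biosynthesis list held 15 genes, of which 7 had a named probe set. Of the 14 listed anthocyanin regulators and the 9 general phenylpropanoid genes, 0 were measured. The results below therefore do not cover the whole pathway. DFR, which encodes dihydroflavonol reductase, fell from 10.08 ± 0.07 to 8.72 ± 0.26 (SD, n = 3), a log2 fold change of -1.35 with an adjusted p of 0.00138. UF3GT, a glycosyltransferase of anthocyanins, changed by -1.49 (adjusted p = 0.00520), and the acyltransferases AT1G03940, AT1G03495 and AT5MAT by -1.64, -0.89 and -1.29. Of the 7 measured members of the anthocyanin biosynthesis list, 6 fell over all probe sets and 6 when adjusted over the list alone, with a median log2 fold change of -1.29; UGT78D2 (-0.19) did not pass. Camera called the list lower with an adjusted p of 4.55e-13, and of 0.00869 with an estimated correlation. AT1G03940 and AT1G03495 are related genes, and probes shared between them would make their separate values uncertain.

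**Figure D1:**
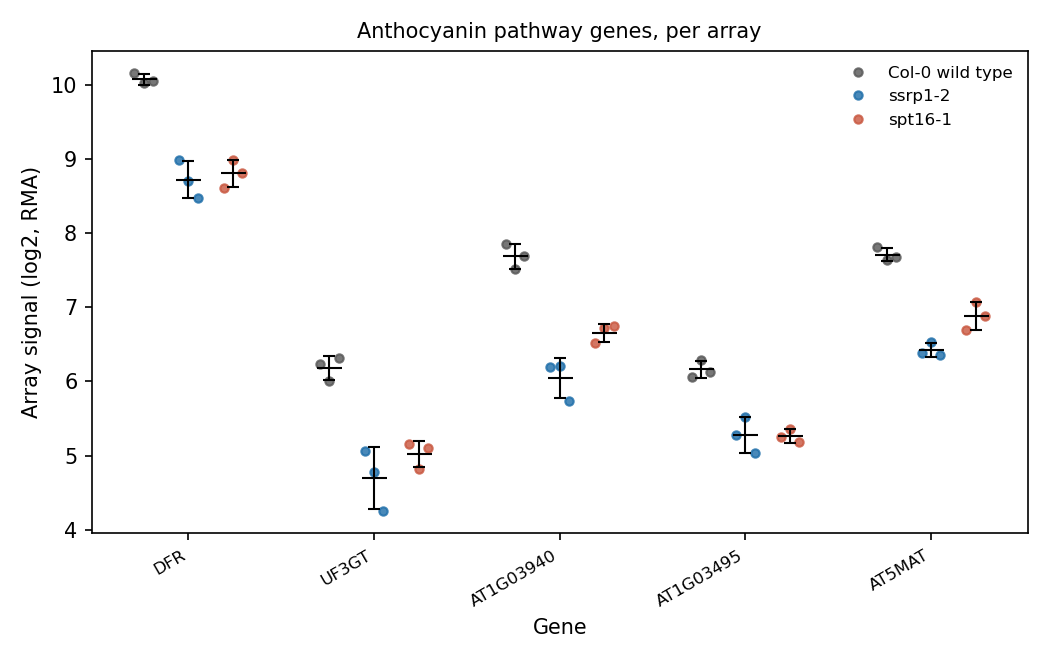
Log2 expression (vertical axis) of 5 members of the anthocyanin biosynthesis list in the 3 genotypes; points are arrays, and the dash with its bar is the mean ± SD over 3 arrays. DFR lies at 10.08 in wild type, 8.72 in ssrp1-2 and 8.81 in spt16-1.

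Among the named genes with the largest decreases in ssrp1-2 were AT1G47395 and its neighbour AT1G47400, which encode small peptides that act in iron signalling. AT1G47395 fell from 8.48 ± 0.10 to 5.52 ± 0.40 (log2 fold change -2.96, adjusted p = 1.04e-04), and AT1G47400 changed by -2.56 (adjusted p = 9.58e-05). BHLH101, a transcription factor of the iron-deficiency response, fell from 6.85 ± 0.14 to 5.01 ± 0.24 (-1.85, adjusted p = 0.00260). AT2G14247 changed by -2.73, the TRAF-like gene AT3G28220 by -1.91 and the jacalin-lectin gene AT1G52000 by -1.60. AT1G12030 (-1.68, adjusted p = 0.00781) also passed, but had an adjusted p of 0.0531 in the unmoderated test.

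The largest increases among named genes in ssrp1-2 included AT2G20142, which encodes a protein with a TIR domain, at 6.18 ± 0.10 against 3.79 ± 0.05 in wild type (5.23-fold, adjusted p = 1.10e-05). STZ, a zinc-finger transcription factor of abiotic stress responses, rose from 5.92 ± 0.16 to 7.98 ± 0.09 (log2 fold change 2.06, adjusted p = 1.04e-04). AT2G24600 rose 4.21-fold, AT1G25400 by 1.75 on the log2 scale, AT1G72416 by 1.61 and AT1G19380 by 1.58. XTH18, a xyloglucan-modifying enzyme of the cell wall, rose by 1.69 (adjusted p = 0.00739), and the calmodulin-like gene CML38 rose too (adjusted p = 0.00939); both calls were lost in the unmoderated test (adjusted p = 0.0516 and 0.0602).

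In all, 735 probe sets differed between ssrp1-2 and wild type (adjusted p under 0.05), 496 higher and 239 lower, of which 102 and 36 changed at least 2-fold. Leaving out 1 of the 6 arrays gave 405 to 501, and the count moved by over 1.5 times without wild-type replicate 1 (480), 2 (427) or 3 (405) and without ssrp1-2 replicate 2 (460) or 3 (441). The intensity trend gave 1190, the unmoderated test 482 and the fit of the 2 genotypes alone 399.

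In spt16-1 the anthocyanin list was also lower than in wild type. DFR stood at 8.81 ± 0.19 (n = 3; log2 fold change -1.27, adjusted p = 0.00224), AT1G03940 changed by -1.03 and AT5MAT by -0.83. UF3GT changed by -1.16 (adjusted p = 0.0202), a call lost without each array other than wild-type replicate 2 (adjusted p up to 0.0856). Of the 7 measured members 5 fell over all probe sets and 6 when adjusted over the list alone, and the median was -0.90. Camera gave an adjusted p of 4.69e-12, and of 0.00541 with an estimated correlation. AT4G14090, an anthocyanin glucosyltransferase, had -0.75 with an adjusted p of 0.0590.

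Cold-induced genes were higher in spt16-1. COR15B rose from 6.40 ± 0.07 to 7.44 ± 0.22 and KIN2 from 8.02 ± 0.21 to 9.06 ± 0.04 (n = 3), log2 fold changes of 1.04 (adjusted p = 0.00217) and 1.03 (adjusted p = 0.00202). In the cold and abscisic acid list 3 of 5 measured members rose over all probe sets and 4 when adjusted over the list alone (median 0.67), and camera called it higher with an adjusted p of 1.76e-08, and of 0.00541 with an estimated correlation. COR47, the other member that rose (0.67, adjusted p = 0.0121), lost its call without wild-type replicate 2 (adjusted p = 0.0555) or 3 (0.0541) and without spt16-1 replicate 2 (0.0533) or 3 (0.0501). KIN1 and KIN2 are neighbouring copies, and shared probes would make their separate values uncertain.

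Several genes at low level in wild type were much higher in spt16-1. AT2G18193, an AAA-type ATPase gene, rose from 2.22 ± 0.21 to 5.28 ± 0.11 (n = 3, adjusted p = 2.06e-05), and the bHLH gene AT5G65320 rose from 2.81 ± 0.18 to 5.88 ± 0.30 (adjusted p = 8.29e-05). SWI1, known for its role in meiosis, rose to 6.05 ± 0.19 (log2 fold change 2.75, adjusted p = 1.39e-04). The wild-type levels of AT2G18193 and AT5G65320 lie below 3.13, within the lowest 25% of probe sets, and were not shown to be above background, so no fold is given for them. AT1G74870, AT5G53230 and AT5G60250 rose by 2.04, 1.53 and 1.51 on the log2 scale. Lower in spt16-1 were AT1G47395 (-1.77), AT1G47400 (-1.71), BHLH101 (-1.75, adjusted p = 0.00410), AT3G28220 (-1.44), AT1G24580 (-1.28) and the senescence-associated sugar transporter gene SAG29 (-1.19, adjusted p = 0.00442).

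Between spt16-1 and wild type 576 probe sets differed, 346 higher and 230 lower, of which 73 and 32 changed at least 2-fold. The count moved by over 1.5 times without each of the 6 arrays: 326, 332 and 340 without wild-type replicates 1, 2 and 3, and 325, 293 and 330 without spt16-1 replicates 1, 2 and 3. The intensity trend gave 1024, the replicate block 380 and the fit of the 2 genotypes alone 271.

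The mutants shared many of these changes. GI, a gene of the circadian clock and of flowering, rose from 7.77 ± 0.05 in wild type to 8.58 ± 0.04 in ssrp1-2 (log2 fold change 0.81, adjusted p = 4.87e-04) and 8.98 ± 0.07 in spt16-1 (1.21, adjusted p = 8.99e-05). AT1G15125 rose by 1.39 and 1.41, AT5G35735 by 1.47 and 1.29, AT1G11070 by 1.48 and 1.83, and the J-domain gene AT1G56300 by 1.31 and 1.99 in ssrp1-2 and spt16-1. AT2G14247 changed by -2.73 and -1.81, and AT1G47400 by -2.56 and -1.71. AT4G36700 passed in both (-2.19 and -2.08), but its call in ssrp1-2 was lost without wild-type replicate 1 or 2 or ssrp1-2 replicate 1 or 3 (adjusted p up to 0.0774), and its call in spt16-1 without each array other than wild-type replicate 3 (adjusted p up to 0.121).

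A total of 275 probe sets passed in both mutants in the same direction, 164 higher and 111 lower, and 2 passed in opposite directions. The shared count moved by over 1.5 times without wild-type replicate 1 (174), 2 (175) or 3 (167) and without spt16-1 replicate 1 (180) or 2 (168); the intensity trend gave 512 and fits of 2 genotypes alone 138. Independent lists of these sizes would share 6.02 higher and 1.93 lower. Unchanged groups simulated against a shared, also simulated, wild-type group shared 0, but they had at most 1 call to share, so that 0 is no baseline for the shared count. Log2 fold changes correlated across probe sets at r = 0.589 against a simulated 0.499, with a covariance of 0.0300 against 0.00958, and 67.8% had the same sign against 66.7% simulated. The covariance exceeded the simulated one, which holds shared simulated controls, by 0.0204. The 3 wild-type arrays are too few to split, and part of the excess over independent lists, which leave the shared controls out, may come from those controls.

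**Figure D2:**
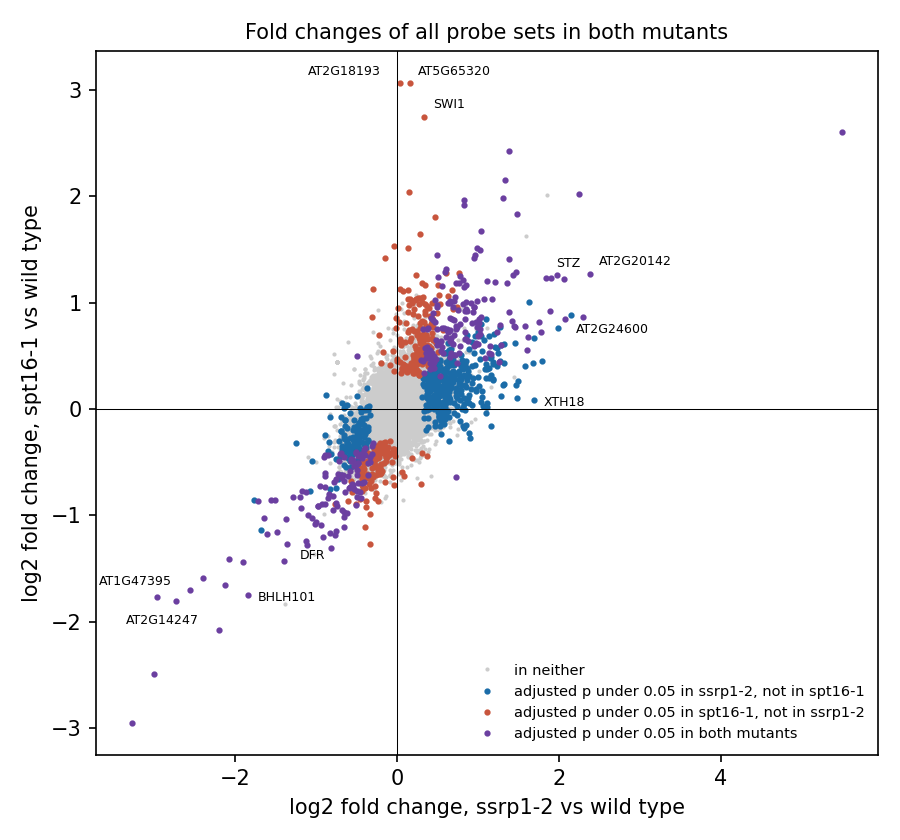
Log2 fold change against wild type of every probe set in ssrp1-2 (horizontal axis) and spt16-1 (vertical axis); each point is a probe set, coloured by the comparisons in which its adjusted p was under 0.05. Purple points passed in both mutants (275 in the same direction and 2 in opposite directions), and AT2G18193, AT5G65320 and SWI1 lie near 0 for ssrp1-2.

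Tested directly against each other, the mutants differed in genes that had changed in spt16-1 and in genes that had changed in ssrp1-2. AT2G18193 (-3.03, adjusted p = 1.36e-04), AT5G65320 (-2.91, adjusted p = 2.54e-04) and SWI1 (-2.41, adjusted p = 7.71e-04) were lower in ssrp1-2 than in spt16-1; against wild type none of the 3 passed in ssrp1-2 (SWI1 0.34). The ssrp1-2 levels of AT2G18193 and AT5G65320 were, like those of wild type, below 3.13 and not shown to be above background, so the sizes of their differences are uncertain and a lack of change in ssrp1-2 was not shown. AT2G24600 (1.23, adjusted p = 0.00386) and AT2G20142 (1.11, adjusted p = 0.00166) were higher in ssrp1-2 than in spt16-1. AT1G47395 was lower in ssrp1-2 (-1.19, adjusted p = 0.0218), a call lost without ssrp1-2 replicate 2 or any 1 of the 3 spt16-1 arrays (adjusted p up to 0.0866). XTH18 stood at 5.19 ± 0.42 in ssrp1-2 and 3.58 ± 0.31 in spt16-1 (n = 3; 1.60, adjusted p = 0.0227), a call lost without each array other than ssrp1-2 replicate 1 (adjusted p up to 0.0895).

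**Figure D3:**
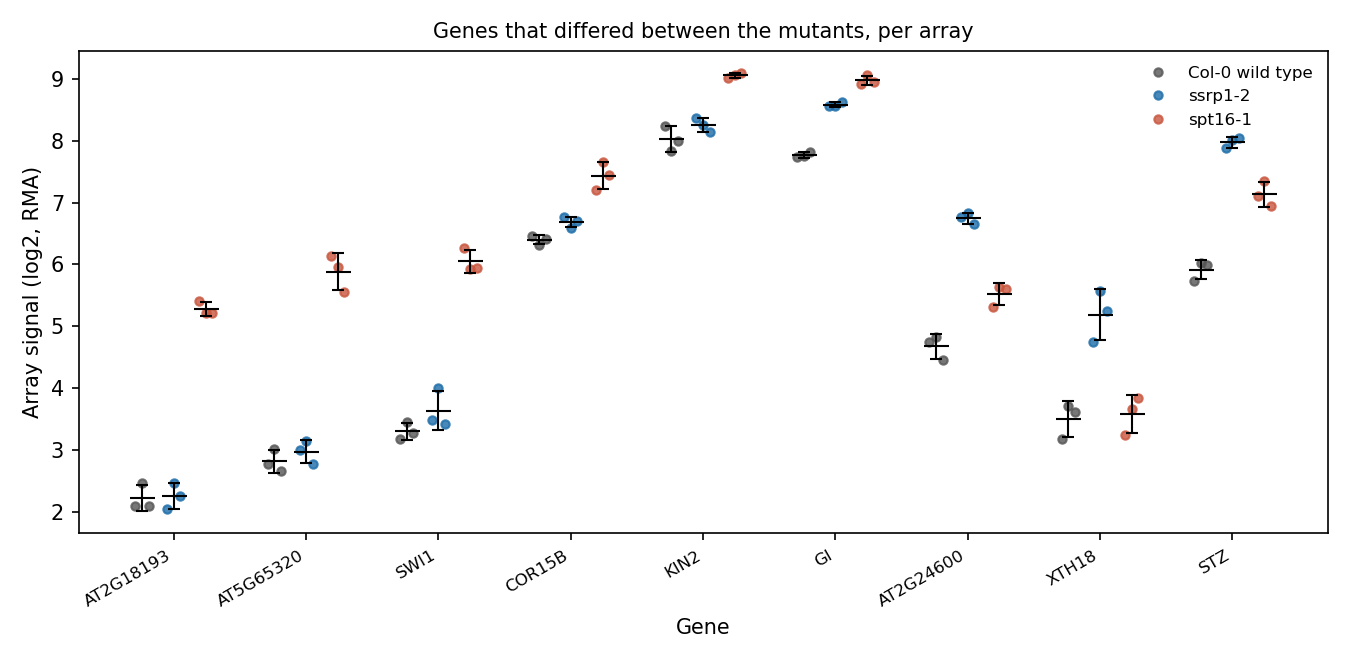
Log2 expression (vertical axis) in the 3 genotypes of 9 genes that differed between the mutants; points are arrays, and the dash with its bar is the mean ± SD over 3 arrays. AT2G18193 lies at 5.28 in spt16-1 and at 2.25 in ssrp1-2, and XTH18 at 5.19 in ssrp1-2 and 3.58 in spt16-1.

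The cold and abscisic acid list was lower in ssrp1-2 than in spt16-1 (camera adjusted p = 1.06e-05, and 0.0188 with an estimated correlation; median -0.36), with 2 of 5 members lower over all probe sets and 3 when adjusted over the list alone. These were COR15B (-0.75, adjusted p = 0.0238), whose call was lost without each array other than spt16-1 replicate 1 (adjusted p up to 0.0877), and KIN2 (-0.80, adjusted p = 0.0169), lost without each array other than ssrp1-2 replicate 1 (adjusted p up to 0.0805). The preset correlation also called the anthocyanin list (adjusted p = 0.0181, median -0.08), histones (0.0181, median -0.17) and mitochondrion-encoded genes (0.00193, median -0.08) lower in ssrp1-2 than in spt16-1. These calls were lost, with adjusted p = 0.230, 0.217 and 0.291 with an estimated correlation. Single arrays also ended them: the anthocyanin call without ssrp1-2 replicate 3 (camera adjusted p = 0.0695) or spt16-1 replicate 2 (0.0602), the histone call without ssrp1-2 replicate 1 (0.107) or 3 (0.0653) or spt16-1 replicate 3 (0.0891), and the mitochondrial call without spt16-1 replicate 1 (0.0777). Over all probe sets 0 of their members passed by limma, and 2, 0 and 0 when adjusted over the list alone.

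The direct comparison gave 238 probe sets, 148 higher and 90 lower in ssrp1-2, with 27 and 19 at least 2-fold. Of the 458 probe sets that passed in ssrp1-2 and not in spt16-1, 104 differed between the mutants, and 59 of the 299 that passed in spt16-1 and not in ssrp1-2. The count was 128, 91 and 110 without ssrp1-2 replicates 1, 2 and 3, and 95, 123 and 94 without spt16-1 replicates 1, 2 and 3. The intensity trend gave 497, the replicate block 117, the unmoderated test 123 and the fit of the 2 genotypes alone 80.

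In ssrp1-2 against wild type the heat shock and high light list was called higher (adjusted p = 0.0485, and adjusted p = 0.156 with an estimated correlation), but of its 4 members only STZ passed (list median 0.06; 1 higher when adjusted over the list alone). The other 3 encode small heat shock proteins. AT1G53540 (2.75 in wild type) and ATHSP22.0 (2.04) lie below 3.13 and AT1G59860 (3.25) just above it, so a lack of change was not shown for them. STZ also rose in spt16-1 (1.22, adjusted p = 0.00134), where the list was not called (adjusted p = 0.0929) except without spt16-1 replicate 3 (0.0163) and by fry (adjusted p = 0.0168). The cold and abscisic acid list was called higher in ssrp1-2 (adjusted p = 0.0429, median 0.29; adjusted p = 0.156 with an estimated correlation) with 0 of 5 members passing and 1 when adjusted over the list alone. Mitochondrion-encoded genes were called lower (adjusted p = 0.0429, median -0.06; adjusted p = 0.430 with an estimated correlation) with 0 of 18 members passing either way; in spt16-1 they were called higher only without spt16-1 replicate 3 (adjusted p = 0.0351). By fry, with all arrays, the heat shock and cold lists were called higher in ssrp1-2 (adjusted p = 0.00201 and 0.00834). Mitochondrion-encoded genes were not called by fry (adjusted p = 0.200). Single arrays decided these ssrp1-2 calls by camera. Without ssrp1-2 replicate 1 or wild-type replicate 2 or 3 the heat shock list had camera adjusted p of 0.157, 0.0545 and 0.0901, the cold list 0.103, 0.0545 and 0.0901, and mitochondrion-encoded genes 0.157, 0.0545 and 0.102. The heat shock and cold calls were also lost without ssrp1-2 replicate 3 (0.0625 each), and all 3 with the replicate block (0.0653, 0.0579 and 0.0579).

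Nuclear photosynthesis genes (7 measured), histones (9) and chloroplast-encoded genes (63) were not called in ssrp1-2 (adjusted p = 0.107, 0.107 and 0.0859) or in spt16-1 (0.357, 0.508 and 0.598). In ssrp1-2 this depended on single arrays: without wild-type replicate 1 photosynthesis (camera adjusted p = 0.0469) and chloroplast-encoded genes (0.00320) were called lower, and without ssrp1-2 replicate 2 histones and chloroplast-encoded genes (0.0373 each). With all arrays, none of their members passed in either mutant, over all probe sets or over the list alone. Of the 3 measured genes of the flavonol branch, UGT73C6 passed in both mutants (-0.31 and -0.35) and AT1G06000 in ssrp1-2 (-0.55); adjusted over the list alone, 3 were lower in ssrp1-2 and 1 in spt16-1. Their calls were not firm: UGT73C6 lost its call without any 1 of the 6 arrays (adjusted p up to 0.103 and 0.0818), and AT1G06000 without wild-type replicate 2 (0.121) or 3 (0.131) and ssrp1-2 replicate 1 (0.109) or 2 (0.111). TRY, a regulator of trichome patterning, had -0.46 in ssrp1-2 and -0.75 in spt16-1 with adjusted p of 0.334 and 0.117. The root marker PYK10 had -0.38 and 0.09, and the flowering repressor SNZ -0.31 and -0.34; neither passed. No measured member of the lists for flowering time (3 genes), root (3), guard cells (3), auxin (3), transcript elongation (2), other histone chaperones (2), trichomes, shoot meristem, jasmonate, indole glucosinolates or the cell cycle (1 each) passed in either mutant over all probe sets. The measured shoot meristem gene CLV3 and jasmonate gene PDF1.2 lie below 3.13 in every genotype, so a lack of change was not shown for them. Adjusted over the list alone, 1 flowering gene in ssrp1-2 and 2 in spt16-1 and 1 root gene in ssrp1-2 were lower. TRY was lower in both mutants only by an unadjusted limma p under 0.05, since its list had 1 measured gene.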

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

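The tests of iron and of wound genes used lists written after the top genes had been seen, and the tests that count labels of plates or harvests were chosen after the labels had been read. The intervals and the reading of the floor used below were added after the values had been seen. Without them, one aberrant spt16-1 array, activation of low-level genes and selection among the iron genes in spt16-1 would have been read as argued against. Handling that varied from sample to sample would have been read so without the limit given below. Selection among the iron genes was split by mutant after the values had been seen too. The other tests were chosen before their results were seen. With 3 arrays per genotype, outliers within a genotype were not tested.

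Genes below differed between the mutants by limma's contrast of ssrp1-2 against spt16-1. AT2G20142 (1.11), AT2G24600 (1.23), AT1G25400 (0.93) and AT1G72416 (1.06) were higher in ssrp1-2, on the log2 scale; AT1G25400 lost its call in the fit of the 2 genotypes alone. STZ (0.84) lost its call without ssrp1-2 replicate 2 or 3 or spt16-1 replicate 1 or 3 (adjusted p up to 0.0821). AT1G19380 (1.17), AT2G01300 (1.14) and XTH18 (1.60) lost theirs without each array other than ssrp1-2 replicate 1, with adjusted p up to 0.0761, 0.112 and 0.0895; the spt16-1 level of AT2G01300 was below 3.13, so its size is uncertain.

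Lower in ssrp1-2 than in spt16-1 were AT2G18193 (-3.03), AT5G65320 (-2.91), SWI1 (-2.41), AT5G53230 (-1.57), AT5G60250 (-1.38) and AT4G33930 (-1.13), with calls kept without any 1 array; the sizes for AT2G18193 and AT5G65320 are taken against levels below 3.13. AT1G56300 (-0.68) lost its call without ssrp1-2 replicate 2 (adjusted p = 0.0511), AT1G47395 (-1.19) with the replicate block and without ssrp1-2 replicate 2 or any 1 spt16-1 array (up to 0.0866), and AT1G47400 (-0.85) without each array other than spt16-1 replicate 2 (up to 0.132). AT1G74870 (-1.89) lost its call in the unmoderated test (adjusted p = 0.0609). GI (-0.40) lost it without any 1 of the 6 arrays (adjusted p up to 0.120), COR15B (-0.75) without each but spt16-1 replicate 1 (up to 0.0877) and KIN2 (-0.80) without each but ssrp1-2 replicate 1 (up to 0.0805).

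Among the fixed lists, the difference between the mutants had a median of -0.08 for anthocyanin biosynthesis, -0.17 for histones, -0.36 for the cold and abscisic acid response and -0.08 for mitochondrion-encoded genes. With an estimated correlation the call of the cold list was kept (adjusted p = 0.0188), and those of the anthocyanin, histone and mitochondrion-encoded lists were lost, with adjusted p = 0.230, 0.217 and 0.291 with an estimated correlation. Among the lists added from the annotation, it was 0.15 for SWEET sugar transporters, 0.21 for the XTH family and 0.11 for the U-box family (camera adjusted p = 0.0191 each). Those 3 calls were lost, with adjusted p = 0.340 each with an estimated correlation.

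Of 10 measured genes known to respond to iron deficiency, 8 fell in ssrp1-2 (median -1.72) and 5 in spt16-1. Among the 8, AT1G13609 (-1.77, limma adjusted p = 0.0331) lost its call without any 1 of the 6 arrays (adjusted p up to 0.124). With each wild-type array left out in turn, 0.930 of the median or more was kept. The list was written after the top genes had been seen. Genes that passed had arrays that did not overlap between genotypes, so a single aberrant wild-type array could hardly carry them. The test therefore cannot decide on such an array. The 3 members outside the largest changes, AT1G74770, AT3G07720 and PYE, had a median of -0.42 in ssrp1-2 (95% interval -0.62 to -0.13) and -0.38 in spt16-1 (-0.65 to -0.09), and fry gave p under 0.05 in both; PYE alone passed, in ssrp1-2 (limma adjusted p = 0.0423). With a bound of -0.1, selection of large changes is narrowly argued against in ssrp1-2 by fry and by the interval of the members' mean over arrays, which ended at -0.11. Camera with an estimated correlation does not share that reading. In spt16-1 selection stays open, as the intervals of the median and of the mean both reach above the bound. Over 3 members the interval of the median only spans their values. Plates or harvests that differed between genotypes stay open, because 0 of the labels that set the groups name a plate or harvest, and so does an effect of the mutations themselves, which was not tested.

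Of 21 measured genes known to respond within minutes to wounding or touch, 9 rose in ssrp1-2 (median 0.69) and 5 in spt16-1 (median 0.23). Selection of large changes is argued against for ssrp1-2 alone. The 13 members outside the largest changes had a median of 0.30 there (95% interval 0.15 to 0.48), with 11 above 0 and 1 passing. In spt16-1 their median was 0.05 (0.01 to 0.20), with 10 above 0 and 1 passing. These intervals of the median are taken over genes and leave out the spread between arrays. The 95% interval of the members' mean over arrays was 0.20 to 0.48 in ssrp1-2. In spt16-1 it was -0.03 to 0.24, which includes 0. Handling that varied from sample to sample stays open, since the mean of those members differed by 4.98 within-group SDs with a 95% interval of 1.76 to 8.11, which reaches below 2. Handling that differed between genotypes throughout cannot be told apart from the mutation, as 0 of the labels that set the groups name a harvest. An effect of the mutation itself stays open and was not tested.

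Some probe sets at low level in wild type, such as those of AT2G18193 and AT5G65320, were higher in spt16-1, which is not a trait of that mutant alone: 26 of 7126 probe sets in the lowest 25% of wild-type level were called higher in spt16-1 and 40 in ssrp1-2, 10 in each by at least 2-fold. Linkage to the mutated locus is argued against, since 0% of the 16 named genes lie within 100 annotated genes of SPT16. One aberrant spt16-1 array stays open: probe sets chosen without replicate 1 departed from wild type in it by 0.571 of the departure in the others (95% interval 0.109 to 1.08; 14 of 17 above the wild-type mean), and those chosen without replicates 2 and 3 by 0.814 (0.421 to 1.22; 9 of 10) and 0.674 (0.320 to 1.38; 11 of 12). All 3 shares exceed 50%, but each interval reaches below it, and the wild-type arrays served both to choose and to measure. Activation of low-level genes beyond that of other genes was not seen, as 320 of the other 21375 probe sets were called higher in spt16-1 (odds ratio 0.241, Fisher's exact p = 3.71e-17), which is not decisive, because calls near the floor were rare in both directions (4 of 7126 against 226 of 21375 lower).

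For the comparisons of 3 arrays against 3, 10 splits of the 6 arrays exist, too few for a share under 0.05. The real counts were 735, 576 and 238, and the highest of the other splits gave 1, 0 and 0. For the 3 genotypes 1 of 100 splits drawn from 280, the real one, gave as many as 892, and the highest other gave 130. That share, under 0.05, argues against a random grouping of the arrays. The splits cannot tell genotype from plates or harvests that differed between genotypes.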

How the results depend on the processing

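The alternatives with 1 probe set per named gene and without identical probe sets were chosen after the data were seen. Counts of changed probe sets moved by over 1.5 times under these settings, given for ssrp1-2 (735), spt16-1 (576) and the mutants against each other (238): intensity trend 1190, 1024 and 497; fits of the 2 groups alone 399, 271 and 80; 1 probe set per named gene 299, 225 and 77, where fewer probe sets were tested; at least 2-fold with adjusted p 138, 105 and 46; at least 2-fold with unadjusted p 150, 111 and 81. The unmoderated test gave 482 for ssrp1-2 and 123 between the mutants. For the 3 genotypes (892), the trend gave 1536 and 1 probe set per gene 327. For the probe sets shared in direction (275), the trend gave 512, fits of 2 groups 138 and 1 probe set per gene 110. Causes other than the fewer probe sets or arrays were not tested. Leaving out 1 array gave 405 to 501, 293 to 340, 91 to 128, 496 to 579 and 167 to 197, with 1 array fewer in each fit.

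Replicate numbers did not pair the arrays: same-number deviations correlated at -0.135 to 0.0692 over 9 pairs, other pairs at -0.112 to 0.0851, and 0 arrays correlated best with their own number in both other genotypes. With the replicate block, counts were 503, 380, 117, 548 and 190, which moved by over 1.5 times for spt16-1, the mutants against each other and the 3 genotypes, and 7 of 93 named-gene calls were lost.

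Lists called in ssrp1-2 (4) dropped to 1 with the estimated correlation, the replicate block, quantile normalization or the lowest 25% left out, and were 1 to 6 without 1 array. In spt16-1 (2) they were 2 to 4 without 1 array. Between the mutants (4) they were 1 with the estimated correlation, 1 with fry and 2 to 4 without 1 array. The anthocyanin list kept its call and direction against wild type under all 11 alternatives beyond the set test, with adjusted p from 1.20e-13 to 1.74e-10 in ssrp1-2 and from 4.21e-12 to 1.04e-09 in spt16-1. Its median was -1.34 to -1.23 and -0.95 to -0.85 without 1 array, with 5 to 6 and 4 to 5 members lower.

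Scaling moved the share of higher calls from 67.5% to 64.5% at most in ssrp1-2 and from 60.1% to 56.6% in spt16-1. Of 93 calls of named genes over the 3 comparisons, 66 held under every alternative run on single genes. Without 1 array 22 were lost, and 0 reversed. The 2-fold minimum was not run on single genes, and calls such as GI in ssrp1-2 (0.81) lie under it. Targeted genes gave no value under any setting, and fits of 2 groups were not run for the 3-genotype count. Genes near the array floor limit what can be called lower: 3 of 7126 probe sets in the lowest 25% of wild-type level were lower in ssrp1-2, against 236 of 21375 others.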

Other observations

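Lists of gene families added from the annotation, and the genes named from them, were chosen after the annotation or the values had been seen and lie outside the rule for named genes.

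Expansins, which loosen cell walls, moved in both directions in ssrp1-2. EXLA1 rose by 1.17 on the log2 scale (limma adjusted p = 2.28e-04), while EXPB3 (-0.70, adjusted p = 0.00131), EXPB1 (-0.57, adjusted p = 0.0161) and EXPA15 (-0.64, adjusted p = 0.0113) fell; the 23 measured members were not called as a list (adjusted p = 0.0611). EXPB3 (-0.41) and EXPB1 (-0.48) also fell in spt16-1. EXLA1 (0.85, adjusted p = 0.00366) and EXPA15 (-0.67, adjusted p = 0.0218) differed between the mutants. Of the 9 XTH genes, XTH33 rose in ssrp1-2 from 4.47 to 5.77 (adjusted p = 6.14e-04), XTH18 rose too, and XTH33 differed from spt16-1 by 1.08 (adjusted p = 0.00444). PUB23, a U-box ubiquitin ligase gene of stress responses, rose by 1.04 in ssrp1-2 (adjusted p = 0.00696) and had 0.07 in spt16-1, a difference of 0.97 (adjusted p = 0.0232).

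WRKY factors were called higher in ssrp1-2 (adjusted p = 0.00359, and adjusted p = 0.347 with an estimated correlation), with WRKY47 (0.70, adjusted p = 0.00915) and WRKY29 (0.58, adjusted p = 0.0314) passing among 7. Cytosolic ribosomal protein genes were called lower in ssrp1-2 (adjusted p = 0.00330, median -0.07; adjusted p = 0.611 with an estimated correlation), but 0 of 132 members passed by limma. In spt16-1 the SWEET sugar transporters were called lower (adjusted p = 0.00347, and adjusted p = 0.507 with an estimated correlation), with SWEET13 (-0.62, adjusted p = 0.0424) passing among 14. The sugar transporter gene SAG29, which fell more in spt16-1 (-1.19, limma adjusted p = 0.00442), is not counted there. The 14 are therefore the genes in the list and not every sugar transporter gene. SAG29 also fell in ssrp1-2 (-0.77, limma adjusted p = 0.0306). That call was lost without each array other than ssrp1-2 replicate 1 (adjusted p up to 0.106).

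The largest increase of any probe set in ssrp1-2 was that of the unnamed 13356037. It stood at 9.59 ± 0.03 in ssrp1-2 and 6.70 ± 0.15 in spt16-1 (n = 3), log2 fold changes of 5.49 and 2.61 (limma adjusted p = 1.18e-06 and 8.29e-05). In spt16-1 the increase of AT2G18193 was larger (3.06). The unnamed 13460963 had the largest decrease in both mutants, -3.28 in ssrp1-2 and -2.95 in spt16-1.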
